A study of Homo sapiens with 32 samples.

How the data were processed

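The deposited files hold, per library and gene, a read count, a CPM value and the length of the longest isoform. Per the submitters' processing notes, reads were called with CASAVA 1.8.2, and aligned to hg19 with TopHat2 2.0.0. The count column holds reads per Entrez gene as the authors deposited them. The CPM column is a signal that the authors made with edgeR, version not stated, by dividing each count by an effective library size, 0.784 to 1.226 of the total; it was used only to check the count column. Per the labels, total RNA was made into cDNA with the Ovation system and digested with S1 endonuclease, and 2 libraries shared a lane. Libraries held 6526604 to 21435232 reads, which limits what can be seen in genes of few reads.

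Counts were tested with edgeR 4.0.16 in R 4.3.3: filterByExpr on the 8 groups, TMM factors and the robust quasi-likelihood test, in 1 fit of 32 libraries with a mean per group and 24 residual degrees of freedom. The 15 comparisons were contrasts of that fit. Genes passed at a Benjamini-Hochberg adjusted p under 0.05 over the 14668 genes of a comparison. The common biological coefficient of variation was 0.405. Donors were not a term of the fit, and a fit with the donor as a block was an alternative. Fold changes against a group of 4 libraries without reads were bounded with 3 reads over the group. Fold changes with 1 library left out are fitted values and were not bounded. Other tools were DESeq2 1.42.0 and limma 3.58.1; tables and figures used Python 3.11.15.

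Gene lists were written before the count files were available. Of 45 lists, 2 matched no gene and 40 were tested with camera at a preset correlation of 0.01, adjusted over 600 tests together, of which 255 passed. Camera with an estimated correlation was the stricter alternative, where 9 passed. Counts of list members use the adjustment over all genes, with the adjustment over the list alone beside them where it differs. Reads of replication histone genes, which are near-identical copies, are split between them with some uncertainty.

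Named genes were chosen by a rule fixed before the data were examined: well-known T cell genes; up to 4 members with the largest fold changes of each list that passed or was counted; and the 6 highest and 6 lowest genes with mean log2 CPM of at least 3 that moved the same way in all donors. Among these, genes whose call held under the alternatives were preferred. The contrasts, the model, the lists and the first set of alternatives were also fixed before the data were examined. The monocyte covariate (log2 of summed monocyte CPM), the removal of each library's GC trend, the block combined with other settings and the list tests without memory day 1 replicate 4 or memory day 14 replicate 3 were chosen after.

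GC content was that of the longest GENCODE v29 transcript of each gene, known for 14347 genes (97.8%), while the files use an older genome build. Removing a GC trend also removes any real change that goes with GC. On simulated negative binomial counts for memory against naive cells at day 0, with 100 genes changed 4-fold and 100 changed 2-fold, edgeR recovered 84% and 36% and called 3 unchanged genes, DESeq2 87% and 45% with 12, and limma-voom 79% and 26% with 8. With an added GC trend, 5212 unchanged genes were called without the correction and 4 with it. Some genes are not reported here and were left out of the tests of single libraries.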

Results

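Gene expression was measured by RNA-seq in human CD4 T cells of 4 donors. Naive cells, which have not met their antigen, and memory cells, which have, were sampled at rest (day 0) and 1, 5 and 14 days after activation with beads that carry antibodies to CD3 and CD28, the antigen receptor complex and its costimulatory partner. Cells kept beyond day 5 received recombinant IL-2, the main growth factor of T cells. The 32 libraries form 8 groups of 4, with 1 library per donor in each group. Total counts ran from 6526604 to 21435232 reads per library. The labels place days 0 and 5 in technical batch 1 and days 1 and 14 in batch 2. The comparisons ask how each cell type changed with time after activation, how memory and naive cells differed on each day, and whether their responses differed. In all 14668 genes had enough reads to be tested and 3600 did not. Values below are group means in CPM, read counts scaled by library totals that were adjusted with TMM factors for differences in composition. Summed CPM of marker genes and percent shares use the plain totals. Changes are log2 fold changes ± SE with 4 libraries in each group. Named genes moved the same way in all 4 donors unless a number of donors is given.

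The libraries of the 2 batches differed in composition. Genes of small non-coding RNAs took 3.90% to 15.6% of the reads in the 16 libraries of batch 2 and 0.125% to 0.394% in the 16 of batch 1. RMRP, the RNA of an enzyme that processes ribosomal and mitochondrial RNA, alone took 1.53% to 6.53% in batch 2 and 0.0460% to 0.167% in batch 1. Genes of ribosomal proteins took 22% to 40.5% of the reads in batch 1 and 7.66% to 13.5% in batch 2. The libraries also differed by GC content. Relative to the mean of all libraries, genes in the highest 20% by GC stood 0.65 to 1.15 log2 units above those in the lowest 20% in batch 2. In batch 1 they stood below them (−1.43 to −0.21). In the fold changes of days 1 and 14 against day 0, which cross the batches, the difference between the highest and the lowest 20% was 2.11 and 2.06 in naive cells and 1.84 and 1.68 in memory cells. It was 0.15 in naive and 0.06 in memory cells at day 5 against day 0, and its size was at most 0.22 in the 8 comparisons of 2 groups within a batch.

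**Figure D1:**
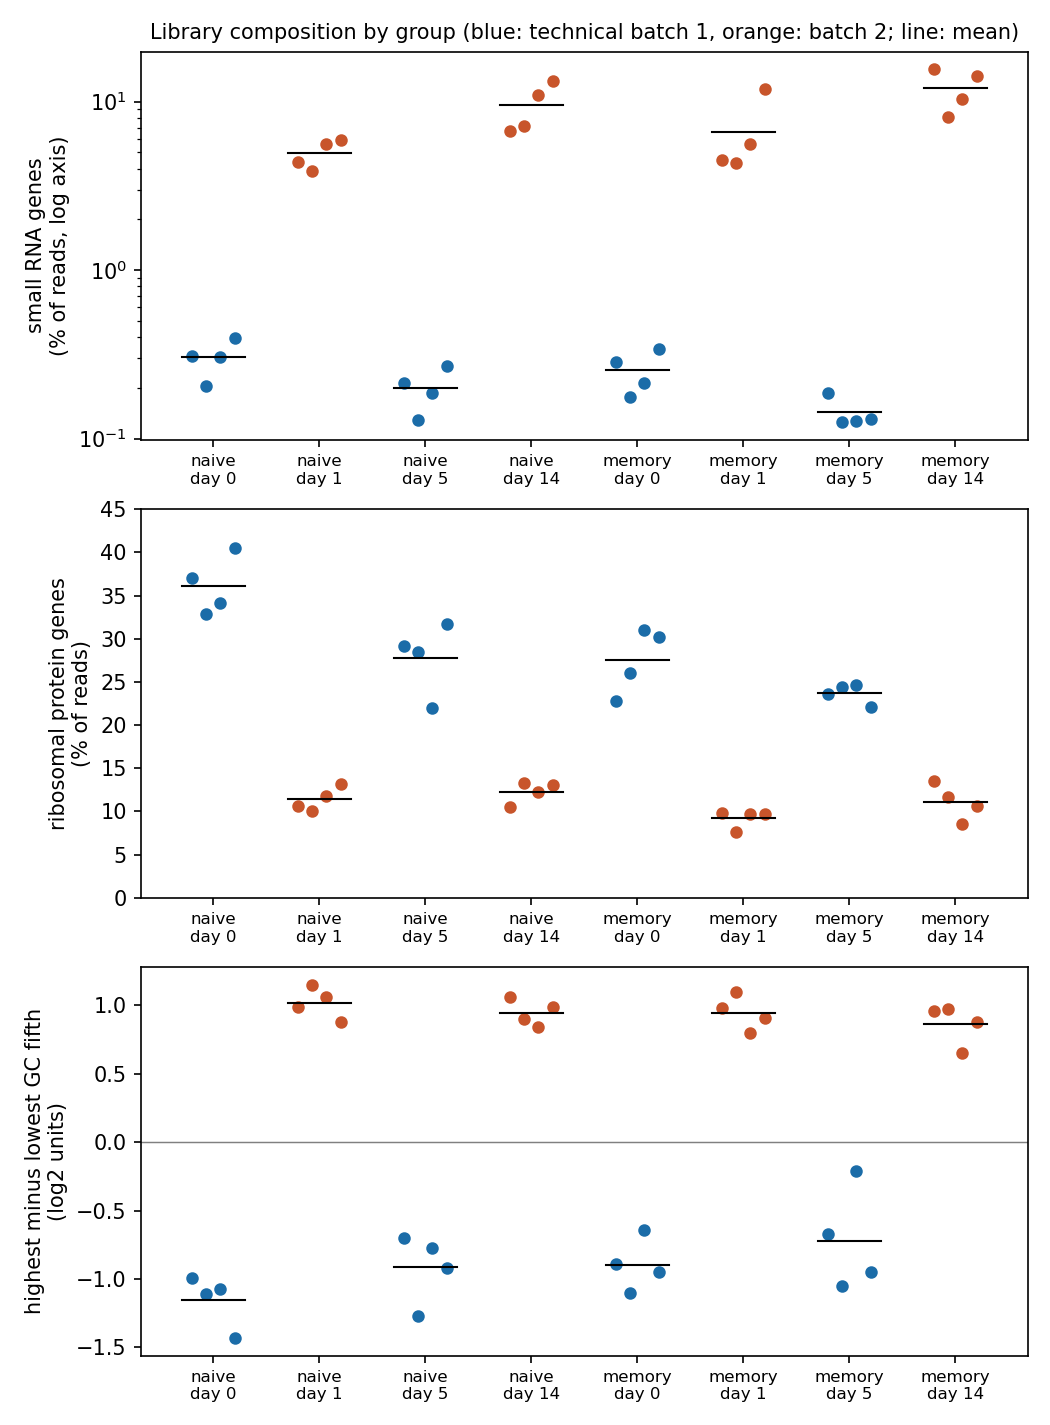
Composition of the 32 libraries by group: the share of reads in small RNA genes (percent, log axis), the share in ribosomal protein genes (percent), and the median deviation of genes in the highest 20% by GC minus that in the lowest (log2 units). Each point is 1 library, black lines are means of 4, blue is batch 1 and orange is batch 2; small RNA shares of batch 2 (3.90% to 15.6%) lie above those of batch 1 (0.125% to 0.394%).

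Markers of other blood cells were present and uneven. The summed CPM of 22 monocyte genes, among them S100A8, VCAN and FCN1, was 11756 ± 13043 (SD, n = 4) in resting memory cells, with 31140, 7616, 3332 and 4935 in replicates 1 to 4, against 730 ± 1111 in resting naive cells (exact two-sided permutation p = 0.0286, the smallest that 4 against 4 can give, adjusted p = 0.0857). At days 5 and 14 the memory libraries stood at 176 ± 167 and 37.7 ± 30.1 CPM, while memory day 1 replicate 4 had 3877. Platelet and red cell genes summed to 3433 CPM in resting memory replicate 2. B cell genes summed to 901 and 732 CPM and plasma cell genes to 763 and 2433 CPM in replicates 2 and 4 of memory day 14. Genes of CD8 cells summed to 314 CPM in replicate 4 of memory day 14. Of 120 such library tests, 10 measures in 12 comparisons, 40 had an unadjusted p of 0.0286 and none passed after Benjamini-Hochberg adjustment.

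**Figure D2:**
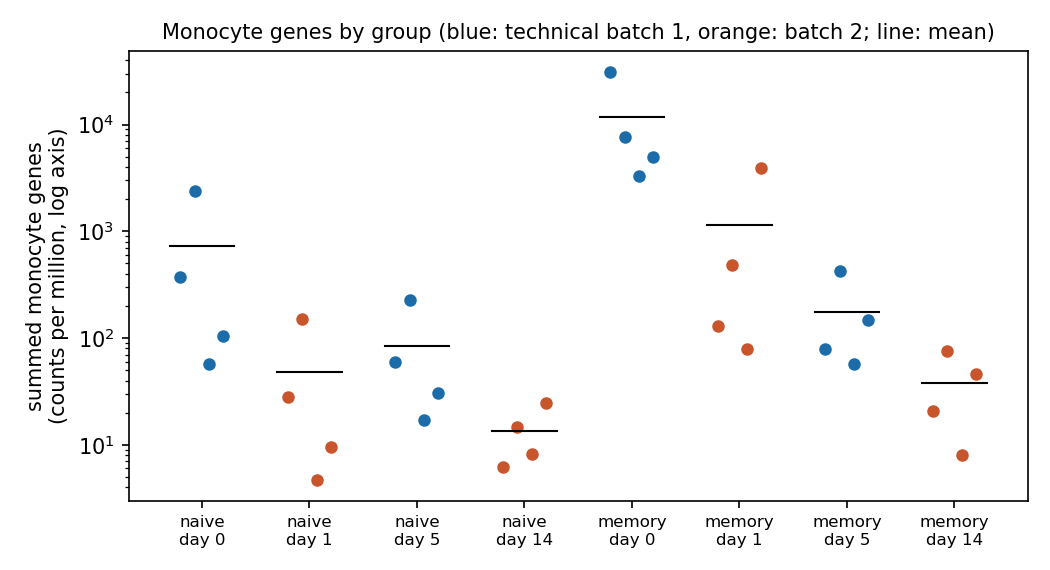
Summed CPM of 22 monocyte genes (log axis) in each of the 32 libraries, by cell type and day. Points are libraries, black lines are means of 4, and resting memory libraries lie between 3332 and 31140.

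In naive cells at day 1 quiescence genes and naive and homing genes fell, and activation surface genes rose. KLF2, which holds T cells in quiescence, fell from 719 to 0.579 CPM (−10.26 ± 1.05), and TCF7, a factor of naive cells, fell from 3120 to 166 (−4.24 ± 0.47). IL2RA, the high-affinity IL-2 receptor chain, rose from 7.05 to 765 CPM (6.75 ± 0.50), IL2 from 0.197 to 81.7 (8.58 ± 1.33), and the cytokine LIF from 0.290 to 358 (10.10 ± 1.13). IRF4, a factor of activated lymphocytes, rose from 14.9 to 1530 CPM (6.67 ± 0.51). The adjusted p of these 6 genes was at most 2.02e-06 for IL2. LIF rose by 11.93 without naive day 0 replicate 1. Of 23 quiescence genes, 19 fell and 1 rose (camera adjusted p = 6.9e-08, and adjusted p = 0.232 with an estimated correlation), among them TXNIP, an inhibitor of glucose uptake (−6.06 ± 0.51). Of 26 naive and homing genes 22 fell and 2 rose (adjusted p = 7.31e-06, and adjusted p = 0.232 with an estimated correlation), including the IL-7 receptor gene IL7R (−2.05 ± 0.48, adjusted p = 0.0005). Of 24 activation surface genes 20 rose and 2 fell (20 and 3 adjusted over the list alone; adjusted p = 0.000197, and adjusted p = 0.281 with an estimated correlation), such as the costimulatory receptor TNFRSF9 (9.77 ± 1.07) and the inhibitory receptors PDCD1 (6.77 ± 0.78) and CTLA4 (3.74 ± 0.51). Of 25 genes of cytokine signalling through JAK and STAT 16 rose and 3 fell (adjusted p = 0.0011, and adjusted p = 0.0744 with an estimated correlation), with CISH at 5.38 ± 0.61 and the survival gene BCL2L1 at 6.48 ± 0.34.

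Biosynthetic genes rose in the same comparison. Of 34 genes of ribosome assembly 32 rose and 1 fell (adjusted p = 1.45e-09, and adjusted p = 0.461 with an estimated correlation), with MYBBP1A at 5.36 ± 0.43. Of 24 genes of one-carbon and nucleotide metabolism 22 rose (adjusted p = 1.22e-06, and adjusted p = 0.454 with an estimated correlation), with CAD, which starts pyrimidine synthesis, at 4.67 ± 0.45 and SHMT2 at 4.14 ± 0.32. Of 22 glycolysis genes 19 rose and 1 fell (adjusted p = 1.01e-06, and adjusted p = 0.415 with an estimated correlation), ENO1 from 213 to 6690 CPM (4.98 ± 0.38) and the hexokinase HK2 by 4.32 ± 0.54. Of 23 cholesterol synthesis genes 18 rose (adjusted p = 0.00021, and adjusted p = 0.609 with an estimated correlation). Of 35 S phase genes 32 rose and 1 fell (adjusted p = 3.07e-07, and adjusted p = 0.645 with an estimated correlation), with the replication licensing genes MCM2 at 7.59 ± 0.74 and CDC6 at 7.91 ± 1.05, and UHRF1, which copies DNA methylation, at 7.47 ± 0.79. Ribosomal protein genes, which also separate the batches, fell in 47 of 53 and rose in 2 (adjusted p = 9.35e-17, and adjusted p = 0.445 with an estimated correlation), RPL34 by −3.76 ± 0.27. MYC rose (2.46 ± 0.36), the amino acid carrier SLC7A5 rose (6.09 ± 0.56), and TBX21, the Th1 factor, rose (5.77 ± 0.80, or 7.19 without naive day 0 replicate 4), while GATA3, the Th2 factor, fell (−2.27 ± 0.50) and FOS, an early response factor, fell from 1980 to 6.20 CPM (−8.32 ± 0.64). MKI67, a proliferation marker (−1.01 ± 0.62, adjusted p = 0.149, lower in 3 of 4 donors), and FOXP3, the regulatory T cell factor (0.09 ± 0.62, adjusted p = 0.904, higher in 3 of 4 donors), did not pass. Lists of cytokines (24 of 39 rose, 4 fell) and of G2 and M phase genes (21 of 34 rose, 2 fell) were not past the list test, at adjusted p = 0.0677 and 0.0606. The cytokine list passed with the monocyte marker level as a covariate (0.0338) and without replicate 1 (0.0437) or 4 (0.042), and the G2 and M phase list without replicate 4 (0.0422). Adjusted over the list alone, the counts of the other lists were the same. In all 5065 genes rose and 4750 fell, 9815 of 14668, and 51.6% of the calls were higher (61.5% with scaling by library size alone). The days are in different batches, so batch and time cannot be told apart. With each library's GC trend removed, 9408 genes passed, 7756 of them shared in the same direction and 92 opposite, and all 27 named genes that changed kept their calls, IL2 shifting most, from 8.58 to 9.95. The G2 and M phase list then passed (adjusted p = 0.00774). Genes whose calls held under the alternatives were preferred for naming, so here and below the named genes do not speak for all calls.

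At day 5 naive cells expressed the genes of dividing cells. MKI67 rose from 4.92 to 599 CPM (6.90 ± 0.73), TOP2A, which untangles DNA in dividing cells, from 2.40 to 419 (7.44 ± 0.57), and CDK1, the kinase of mitosis, from 0.412 to 111 (7.97 ± 0.78). Of 34 G2 and M phase genes 33 rose and 1 fell (adjusted p = 1.09e-32, and adjusted p = 0.101 with an estimated correlation), DLGAP5 by 8.11 ± 0.73. Of 35 S phase genes 33 rose (adjusted p = 6.27e-15, and adjusted p = 0.415 with an estimated correlation), TK1 by 7.15 ± 0.76 and RRM2 by 6.55 ± 0.75. The inhibitory receptor LAG3 rose from 5.07 to 920 CPM (7.49 ± 0.59), FOXP3 from 20.2 to 424 (4.39 ± 0.70), and GZMB, a protease of cytotoxic granules, from 22.4 to 484 (4.43 ± 0.89). Of 17 regulatory T cell genes 10 rose and 1 fell (11 and 1 adjusted over the list alone; adjusted p = 0.000103, and adjusted p = 0.0536 with an estimated correlation). Of 24 activation surface genes 20 rose and 1 fell (adjusted p = 7.17e-11, and adjusted p = 0.0535 with an estimated correlation), with IL2RA at 7.07 ± 0.50, PDCD1 at 7.07 ± 0.79, CD70 at 7.91 ± 0.82 and the death receptor FAS at 2.54 ± 0.31. The factors EGR3 (7.17 ± 0.81) and IRF4 (5.08 ± 0.47) rose. Without naive day 0 replicate 2, CDK1 rose by 9.01 and GZMB by 5.57. Of 23 quiescence genes 20 fell (adjusted p = 6.73e-13, and adjusted p = 0.0857 with an estimated correlation), KLF2 by −8.63 ± 0.98, and TCF7 (−3.43 ± 0.45) and the exit receptor S1PR1 (−2.08 ± 0.31) fell as well.

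Metabolic genes rose at day 5 too. Of 22 glycolysis genes 21 rose (adjusted p = 7.63e-13, and adjusted p = 0.19 with an estimated correlation), GAPDH from 924 to 11200 CPM (3.61 ± 0.31). Of 30 respiratory chain genes 25 rose (adjusted p = 3.59e-07, and adjusted p = 0.479 with an estimated correlation), NDUFV2 by 3.23 ± 0.31. Cholesterol genes rose in 21 of 23 (adjusted p = 7.3e-09, and adjusted p = 0.357 with an estimated correlation), SQLE by 4.60 ± 0.43. Of 24 one-carbon and nucleotide genes 18 rose (adjusted p = 1.22e-06, and adjusted p = 0.45 with an estimated correlation), with the serine synthesis enzymes PHGDH at 4.92 ± 0.64 and PSAT1 at 5.21 ± 0.75. Ribosomal protein genes fell in 27 of 53 and rose in 1 (adjusted p = 0.000497, and adjusted p = 0.817 with an estimated correlation). Monocyte genes fell in 19 of 22 (19 fell and 1 rose adjusted over the list alone; adjusted p = 0.00956, and adjusted p = 0.81 with an estimated correlation). The median log2 fold change was −5.58, or −5.52 with genes absent from a group at their bound. The other counts were the same adjusted over the list alone. In all 3918 genes rose and 3535 fell, 52.6% of the calls higher (60.5% with scaling by library size alone). Both days are in batch 1.

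At day 14 replication-dependent histone genes, transcribed as DNA is copied, stood highest in naive cells. Their share of reads averaged 0.028% at day 0 and 0.0681% at day 5 in batch 1, and 0.135% at day 1 and 2.77% at day 14 in batch 2. It was lower at day 5, when MKI67 was up, than at day 1, when MKI67 was not. The part of the batch in their rise from day 0 cannot be told from that of time. HIST1H1B rose from 1.03 to 2350 CPM (11.15 ± 0.62) and HIST1H2AJ from 0.355 to 1200 (11.70 ± 0.63), and all 22 such genes rose (adjusted p = 3.84e-27, and adjusted p = 0.069 with an estimated correlation). G2 and M phase genes rose in 33 of 34 and fell in 1 (adjusted p = 1.07e-14, and adjusted p = 0.383 with an estimated correlation), MKI67 from 4.92 to 334 CPM (6.06 ± 0.70) and KIF2C by 7.25 ± 0.69 (8.40 without naive day 0 replicate 3). S phase genes rose in 29 of 35 (adjusted p = 5.61e-06, and adjusted p = 0.677 with an estimated correlation), TYMS by 7.34 ± 0.78. CDKN2C, an inhibitor of cell cycle kinases, rose by 4.68 ± 0.45. CD4, the co-receptor of these cells, rose 3.49-fold, from 176 to 614 CPM (adjusted p = 1.25e-08), IL9R by 5.31 ± 0.88 and PRF1, the pore-forming protein of cytotoxic granules, by 4.42 ± 0.65. Activation surface genes rose in 18 of 24 and fell in 2 (adjusted p = 0.0122, and adjusted p = 0.513 with an estimated correlation), IL2RA by 4.04 ± 0.44 and PDCD1 by 5.12 ± 0.77, and IRF4 rose by 3.24 ± 0.44. CD69, an early activation and retention marker, fell from 1820 to 19.8 CPM (−6.52 ± 0.48), FOS from 1980 to 3.41 (−9.22 ± 0.67), FHIT by −4.27 ± 0.55 and TCF7 by −2.81 ± 0.44. Glycolysis genes rose in 17 of 22 and fell in 1 (19 and 1 adjusted over the list alone; adjusted p = 0.000531, and adjusted p = 0.603 with an estimated correlation). Ribosomal protein genes fell in 46 of 53 and rose in 2 (adjusted p = 1.8e-19, and adjusted p = 0.415 with an estimated correlation), RPL22 by −3.73 ± 0.23, across the batches that differ in the share of these genes. IL7R stood at 235 against 215 CPM (0.13 ± 0.47, adjusted p = 0.827, higher in 3 of 4 donors). The other counts were the same adjusted over the list alone. In all 4550 genes rose and 4283 fell, and 51.5% of the calls were higher (63.1% with scaling by library size alone). Batch and time cannot be told apart. With the GC trend removed 8015 genes passed, 6249 shared in the same direction and 80 opposite, and all 17 named genes that changed kept their calls, CD69 shifting most, from −6.52 to −5.29.

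Between days 1 and 14, both in batch 2, naive cells regained part of the resting program while histone and mitotic genes rose. KLF2 rose from 0.579 to 189 CPM (8.33 ± 0.99), IL7R from 51.9 to 235 (2.18 ± 0.49), S1PR1 from 186 to 397 (1.09 ± 0.30, adjusted p = 0.00334) and LRRN3, a gene of naive cells, from 7.71 to 295 (5.26 ± 0.54). Of 23 quiescence genes 16 rose (17 adjusted over the list alone; adjusted p = 7.34e-08, and adjusted p = 0.232 with an estimated correlation), with PIK3IP1, an inhibitor of PI3 kinase, at 4.15 ± 0.53. All 22 replication histone genes rose (adjusted p = 5.7e-34, and adjusted p = 0.0454 with an estimated correlation), HIST1H1B by 7.04 ± 0.51, and 32 of 34 G2 and M phase genes rose (adjusted p = 1.14e-18, and adjusted p = 0.272 with an estimated correlation), MKI67 from 2.48 to 334 CPM (7.07 ± 0.74) and PLK1 by 7.26 ± 0.59. Inhibitors of cyclin-dependent kinases rose in 5 of 10 (adjusted p = 0.000465, and adjusted p = 0.0536 with an estimated correlation), CDKN2C by 6.47 ± 0.50 and CDKN1B by 2.79 ± 0.33. Ribosome assembly genes fell in 33 of 34 (33 fell and 1 rose adjusted over the list alone; adjusted p = 2.03e-20, and adjusted p = 0.226 with an estimated correlation), RRP12 by −3.60 ± 0.52. Early response factors fell in 20 of 29 (20 fell and 1 rose adjusted over the list alone; adjusted p = 1.25e-07, and adjusted p = 0.232 with an estimated correlation), IRF4 by −3.42 ± 0.43 and MYC by −2.22 ± 0.36. IL2 fell from 81.7 to 0.384 CPM (−7.71 ± 1.22), IL2RA from 765 to 117 (−2.71 ± 0.41), TNFRSF9 by −4.85 ± 0.78 (−6.19 without naive day 14 replicate 4), CTLA4 by −2.35 ± 0.47 and ENO1 by −2.02 ± 0.33. Respiratory chain genes fell in 23 of 30 and rose in 2 (24 and 2 adjusted over the list alone; adjusted p = 1.68e-05, and adjusted p = 0.593 with an estimated correlation), CYCS, cytochrome c, by −2.60 ± 0.44. Of 38 genes known to be higher in memory than in naive cells 25 rose and 3 fell (adjusted p = 1.2e-05, and adjusted p = 0.429 with an estimated correlation), with the calcium-binding S100A4 at 5.46 ± 0.62 and AHNAK at 4.57 ± 0.57. The other counts were the same adjusted over the list alone. In all 3280 genes rose and 3507 fell.

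**Figure D3:**
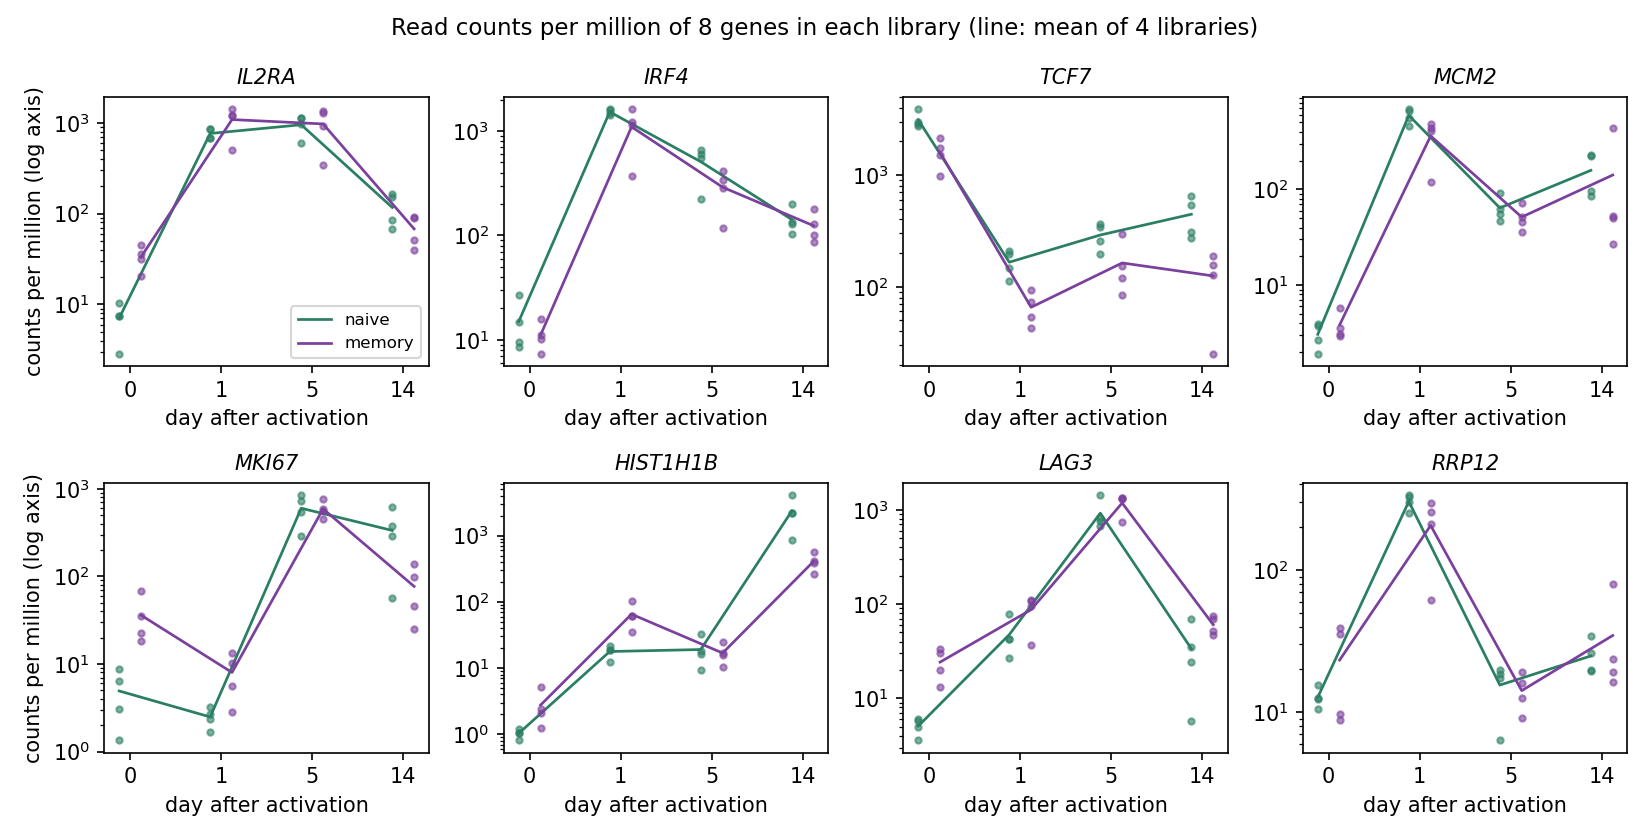
CPM (log axis) of IL2RA, IRF4, TCF7, MCM2, MKI67, HIST1H1B, LAG3 and RRP12 by day after activation in naive (green) and memory (purple) cells. Points are libraries and lines join means of 4; HIST1H1B averages 2350 in naive and 409 in memory cells at day 14, and IL2RA 765 and 1090 at day 1.

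In memory cells at day 1, cytokine genes rose steeply. IL17F, a Th17 cytokine, rose from 0.236 to 363 CPM (10.72 ± 1.55), IL17A from 1.36 to 136 (6.69 ± 1.29, adjusted p = 5.47e-05), IL13, a Th2 cytokine, from 0.131 to 60.6 (8.90 ± 1.22), IL10, an anti-inflammatory cytokine, from 2.10 to 235 (6.82 ± 1.15) and LIF from 0.594 to 768 (10.40 ± 1.11). Without memory day 0 replicate 2, the highest for both at 4.92 and 5.30 CPM with 0.540 and 1.33 in the nearest library, IL17A rose by 9.72 and IL10 by 7.80. The fitted rise of IL17F was 15.17 without memory day 0 replicate 4, a value not bounded with 3 reads, so its size is not reliable. IL9 and IL21, without a read in the 4 resting memory libraries, were at least 3100-fold and at least 279-fold higher at day 1 against a floor of 3 reads over the group. Of 39 cytokine genes 27 rose and 2 fell (adjusted p = 0.00844, and adjusted p = 0.664 with an estimated correlation), including TNF (5.82 ± 0.64) and LTA (6.06 ± 0.66). The list's median log2 fold change was 4.95, or 4.38 with absent genes at their bound. GZMB rose from 16.0 to 845 CPM (5.73 ± 0.95). Of 24 activation surface genes 20 rose and 2 fell (adjusted p = 0.000248, and adjusted p = 0.302 with an estimated correlation), IL2RA from 33.3 to 1090 CPM (5.03 ± 0.45) and CTLA4 by 4.58 ± 0.52. Genes of JAK and STAT signalling rose in 18 of 25 and fell in 2 (18 and 3 adjusted over the list alone; adjusted p = 0.000103, and adjusted p = 0.0535 with an estimated correlation), BCL2L1 by 4.79 ± 0.32. IRF4 (6.63 ± 0.51) and the lymph node homing receptor CCR7 (2.23 ± 0.38) rose. Quiescence genes fell in 16 of 23 and rose in 1 (17 and 1 adjusted over the list alone; adjusted p = 9.46e-06, and adjusted p = 0.357 with an estimated correlation), KLF2 by −5.84 ± 0.85 and TXNIP by −4.30 ± 0.46, and TCF7 (−4.60 ± 0.48), GATA3 (−3.12 ± 0.51), FOS (−8.45 ± 0.64) and MKI67 (36.1 to 8 CPM, −2.16 ± 0.59, adjusted p = 0.00237) fell.

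Ribosome assembly genes rose in 29 of 34 in memory cells at day 1 and fell in 2 (30 and 2 adjusted over the list alone; adjusted p = 3.92e-08, and adjusted p = 0.532 with an estimated correlation), BOP1 by 4.42 ± 0.45. S phase genes rose in 31 of 35 (32 adjusted over the list alone; adjusted p = 6.94e-06, and adjusted p = 0.677 with an estimated correlation), MCM2 by 6.56 ± 0.71. Glycolysis genes rose in 18 of 22, with 1 lower (adjusted p = 4.35e-05, and adjusted p = 0.513 with an estimated correlation), ENO1 by 4.01 ± 0.36. SLC7A11, which imports cystine, rose by 8.36 ± 1.40 (12.37 without memory day 0 replicate 2). Ribosomal protein genes, lower in batch 2, fell in 46 of 53 and rose in 2 (adjusted p = 3.7e-18, and adjusted p = 0.429 with an estimated correlation), RPL22 by −3.54 ± 0.23. CAMP, a peptide of neutrophil granules, fell from 117 to 0.0726 CPM (−10.73 ± 0.98), and S100A12, of monocytes and neutrophils, from 185 to 1.41 (−7.22 ± 1.34), beside the monocyte markers that were high in resting memory libraries. The other counts of both parts were the same adjusted over the list alone. Memory day 1 replicate 4, the library of that group with the fewest reads, had 503.7 CPM of IL2RA and 374.3 of IRF4, against 1198 to 1432 and 1151 to 1633 in the other 3. It had 30.6 CPM of KLF2, against 3.86 in the nearest, and without it KLF2 fell by −7.60 and S100A12 by −9.74. In all 4760 genes rose and 4436 fell, 51.8% of the calls higher (62.4% with scaling by library size alone). Batch and time cannot be told apart. With the GC trend removed 8684 genes passed, 7142 shared in the same direction and 32 opposite, and all 28 named genes kept their calls, SLC7A11 shifting most, from 8.36 to 9.41.

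At day 5 memory cells expressed mitotic and metabolic genes. MKI67 rose from 36.1 to 589 CPM (4.03 ± 0.63), AURKB, a mitotic kinase, by 5.54 ± 0.58 and KIF20A by 6.15 ± 0.68. Of 34 G2 and M phase genes 33 rose and 1 fell (adjusted p = 1.06e-28, and adjusted p = 0.114 with an estimated correlation). All 35 S phase genes rose (adjusted p = 9.77e-17, and adjusted p = 0.383 with an estimated correlation), TYMS, the thymidylate synthase, by 5.34 ± 0.70 and the licensing factor CDT1 by 5.03 ± 0.61. LAG3 rose from 24.2 to 1180 CPM (5.61 ± 0.54), IL2RA from 33.3 to 975 (4.87 ± 0.45), GZMB by 5.59 ± 0.95, ZBED2 by 7.68 ± 0.84 and CCR7 by 2.08 ± 0.38. Of 24 activation surface genes 18 rose and 1 fell (19 and 1 adjusted over the list alone; adjusted p = 1.04e-07, and adjusted p = 0.101 with an estimated correlation). Quiescence genes fell in 21 of 23 (adjusted p = 3.39e-12, and adjusted p = 0.0884 with an estimated correlation), KLF2 by −5.98 ± 0.86, and IL7R fell from 227 to 14.9 CPM (−3.93 ± 0.53) and TCF7 by −3.28 ± 0.45. Glycolysis genes rose in 19 of 22 (20 adjusted over the list alone; adjusted p = 5.37e-10, and adjusted p = 0.279 with an estimated correlation), ALDOC by 3.22 ± 0.44. Respiratory chain genes rose in 25 of 30 (adjusted p = 8.24e-08, and adjusted p = 0.445 with an estimated correlation), NDUFV2 by 2.93 ± 0.31. One-carbon and nucleotide genes rose in 18 of 24 and fell in 1 (19 and 1 adjusted over the list alone; adjusted p = 1.2e-08, and adjusted p = 0.375 with an estimated correlation), PHGDH by 5.76 ± 0.68. Cholesterol genes rose in 20 of 23 (adjusted p = 6.27e-08, and adjusted p = 0.397 with an estimated correlation). Monocyte genes fell in 21 of 22 (adjusted p = 8.98e-07, and adjusted p = 0.532 with an estimated correlation), VCAN from 1260 to 1.14 CPM (−10.08 ± 1.63) and FCN1 by −9.88 ± 1.58 (−8.81 and −8.87 without memory day 0 replicate 1). Without memory day 5 replicate 1 KLF2 fell by −7.56. Platelet and red cell genes fell in 9 of 10 (10 adjusted over the list alone; adjusted p = 0.00436, and adjusted p = 0.598 with an estimated correlation), PF4, a platelet chemokine, by −8.93 ± 1.43. The other counts were the same adjusted over the list alone. In all 3556 genes rose and 3390 fell, within batch 1, 51.2% of the calls higher (58.7% with scaling by library size alone). With the monocyte marker level as a covariate 3750 genes passed.

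At day 14 memory cells had raised histone genes like naive cells. The histone share averaged 0.0308% at day 0 and 0.0771% at day 5 in batch 1. In batch 2 it was 0.208% at day 1 and 0.919% at day 14. HIST1H3F rose from 0.466 to 205 CPM (8.77 ± 0.70) and HIST1H3G from 0.309 to 193 (9.21 ± 0.73), and all 22 replication histone genes rose (adjusted p = 1.9e-20, and adjusted p = 0.101 with an estimated correlation). CD4 rose by 1.59 ± 0.20, the IL-4 receptor IL4R by 3.02 ± 0.28, ZAP70, the kinase of the antigen receptor, by 3.45 ± 0.33, the chemokine receptor CXCR6 by 3.75 ± 0.94, CD70 by 3.66 ± 0.61 and IRF4 by 3.48 ± 0.44. FOXP3 fell from 68.2 to 10.5 CPM (−2.69 ± 0.66, adjusted p = 0.000947), TCF7 by −3.67 ± 0.46, FOS by −9.63 ± 0.68, CD69 by −6.71 ± 0.48 and S100A10 by −4.68 ± 0.37. MKI67 stood at 76.8 against 36.1 CPM (1.09 ± 0.57, adjusted p = 0.0997, and 1.15 with adjusted p = 0.0284 with the donor as a block). It also passed with scaling by library size alone and without memory day 0 replicate 2 or memory day 14 replicate 1. S phase genes rose in 27 of 35 (adjusted p = 0.00212, and adjusted p = 0.816 with an estimated correlation) and G2 and M phase genes in 26 of 34, with 1 lower (adjusted p = 0.000541, and adjusted p = 0.762 with an estimated correlation). With the monocyte marker level as a covariate these lists had adjusted p of 0.821 and 0.454. Memory day 14 replicate 3 stood apart, with MCM2 at 434.4 CPM against 26.9 to 52.81 in the other 3 libraries and TCF7 at 24.95 against 128.1 to 188.7. Without it 18 S phase genes rose and 2 fell (adjusted p = 0.0277), 23 G2 and M phase genes rose and 1 fell (adjusted p = 0.00563), and TCF7 kept its call. Ribosomal protein genes, lower in batch 2, fell in 46 of 53 and rose in 2 (46 and 3 adjusted over the list alone; adjusted p = 9.35e-17, and adjusted p = 0.445 with an estimated correlation), RPL22 by −3.34 ± 0.23. The B cell gene CD79A (5.40 to 164 CPM, 4.92 ± 0.74) rose, with B cell genes highest in replicates 2 and 4. Monocyte genes fell in 21 of 22 (adjusted p = 2.02e-05, and adjusted p = 0.612 with an estimated correlation), S100A8 from 2210 to 0.173 CPM (−13.70 ± 1.92), and PF4 fell by −11.50 ± 1.72. HIST1H3G rose by 11.96 and CD70 by 4.80 without memory day 0 replicate 3, and S100A8 fell by −14.81 without memory day 14 replicate 4. The median of the monocyte genes was −9.37, or −8.41 with absent genes at their bound. The other counts were the same adjusted over the list alone. In all 4356 genes rose and 4154 fell, 51.2% of the calls higher (64.7% with scaling by library size alone), and 5363 genes passed with the covariate. Batch and time cannot be told apart. With the GC trend removed 7954 genes passed, 6471 shared in the same direction and 16 opposite, and all 17 named genes that changed kept their calls, CD69 shifting most, from −6.71 to −5.74.

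From day 1 to day 14, within batch 2, cytokine genes fell in memory cells. IL2 fell from 65.6 to 0.143 CPM (−8.49 ± 1.33), IL17F from 363 to 0.587 (−9.29 ± 1.40), IL10 from 235 to 1.31 (−7.38 ± 1.18), IL17A by −6.48 ± 1.27, IL13 by −4.09 ± 0.87 and GZMB by −4.29 ± 0.89. Of 39 cytokine genes 27 fell and 1 rose (adjusted p = 9.15e-07, and adjusted p = 0.356 with an estimated correlation), LTA by −5.54 ± 0.64. Of 16 Th17 genes 9 fell and 1 rose (adjusted p = 0.00253, and adjusted p = 0.397 with an estimated correlation). Activation surface genes fell in 17 of 24 and rose in 1 (adjusted p = 6.33e-09, and adjusted p = 0.0766 with an estimated correlation), IL2RA from 1090 to 68.0 CPM (−4.00 ± 0.43), CTLA4 by −3.78 ± 0.50 and TNFRSF4 by −4.39 ± 0.56. Early response factors fell in 19 of 29 (22 adjusted over the list alone; adjusted p = 1.17e-10, and adjusted p = 0.138 with an estimated correlation), IRF4 by −3.15 ± 0.43. Ribosome assembly genes fell in 32 of 34 (33 adjusted over the list alone; adjusted p = 1.39e-14, and adjusted p = 0.337 with an estimated correlation), RRP12 by −2.56 ± 0.50. All 22 replication histone genes rose (adjusted p = 1.95e-18, and adjusted p = 0.101 with an estimated correlation), as did 29 of 34 G2 and M phase genes (adjusted p = 3.53e-13, and adjusted p = 0.383 with an estimated correlation), MKI67 by 3.25 ± 0.61 and PLK1 by 3.54 ± 0.50. Quiescence genes rose in 12 of 23 and fell in 2 (13 and 2 adjusted over the list alone; adjusted p = 7.07e-05, and adjusted p = 0.42 with an estimated correlation), KLF2 by 4.05 ± 0.79. SLFN5 (3.14 ± 0.43), KLRB1, a receptor of Th17 and other memory cells (4.24 ± 0.95), CD27 (2.22 ± 0.36) and CDKN2C (3.38 ± 0.44) rose, and CCR7 fell (−1.97 ± 0.37). B cell genes rose in 10 of 14 and fell in 1 (11 and 1 adjusted over the list alone; adjusted p = 0.00401, and adjusted p = 0.532 with an estimated correlation), CD79A by 5.47 ± 0.76, and IGJ, the joining chain of plasma cell antibodies, by 9.82 ± 2.12. Monocyte genes fell in 20 of 22 (22 adjusted over the list alone; adjusted p = 8.12e-06, and adjusted p = 0.598 with an estimated correlation), with 3877 CPM of them in memory day 1 replicate 4. Their median was −6.37, or −6.09 with absent genes at their bound. The other counts were the same adjusted over the list alone. Without memory day 14 replicate 3, 19 G2 and M phase genes rose, and the Th17 list did not pass (adjusted p = 0.0515). IL2, which was counted in that library, then fell by a fitted −12.72, a value not bounded with 3 reads, so its size is not reliable. Of 35 S phase genes 1 rose and 3 fell (camera adjusted p = 0.00243), and without that library 30 fell (adjusted p = 3.4e-12). KLF2 rose by 5.82, KLRB1 by 5.51 and IGJ by 11.76 without memory day 1 replicate 4. In all 2190 genes rose and 2470 fell. Without replicate 1 the 4660 calls became 2006 and without replicate 2 they became 2416.

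Naive and memory cells shared most of their calls. At day 1 against day 0, 4172 genes rose in both, 82.4% of those of naive and 87.6% of those of memory cells, where independent lists of these sizes would share 1643.7. In the same way 3822 fell in both, against 1436.5. At day 5 the shared genes were 2817 higher, against 949.9, and 2413 lower, against 817. At day 14 they were 3664 and 3356, against 1351.2 and 1213. Between 6 and 22 genes of each list moved in opposite directions. The resting libraries of the 2 cell types are separate, but days 1 and 14 share the batch difference from day 0 in both, and this part of the overlap cannot be told from the response.

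**Figure D4:**
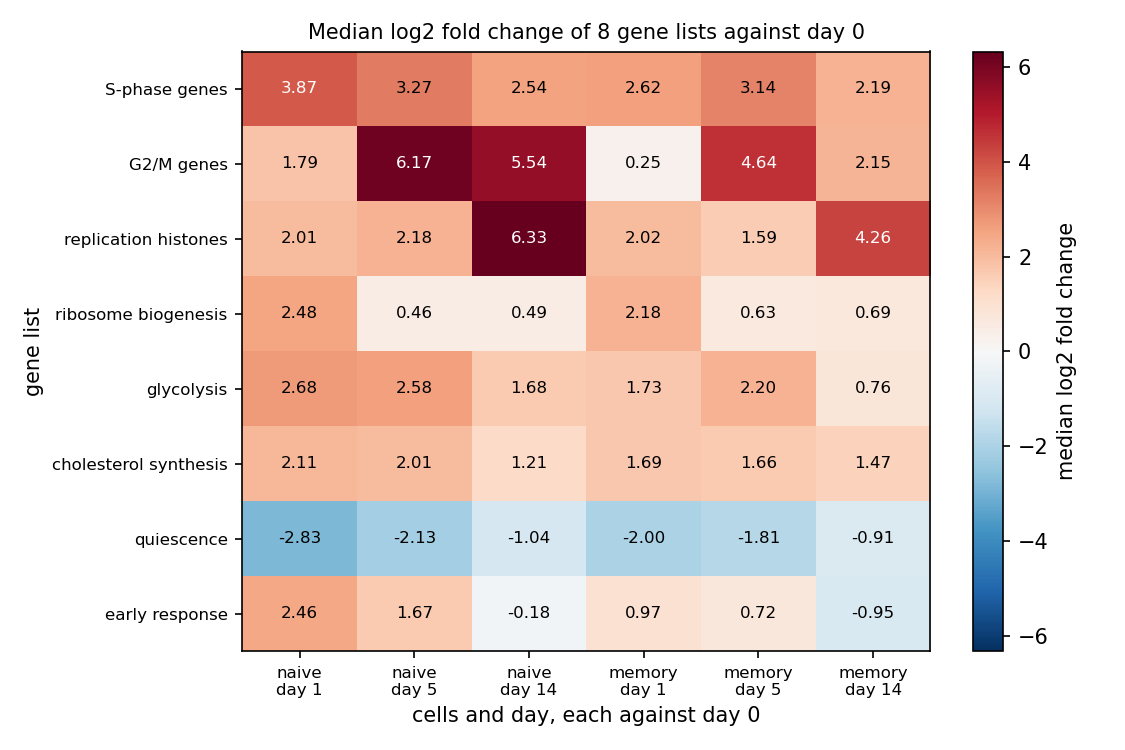
Median log2 fold change against day 0 of 8 gene lists in naive and memory cells at days 1, 5 and 14, with the value in each cell and red for higher. Replication histone genes reach 6.33 in naive and 4.26 in memory cells at day 14, and G2 and M phase genes 6.17 and 4.64 at day 5. Days 1 and 14 are in another batch than day 0, and day 5 is in the same one.

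At rest, memory cells stood above naive cells in genes of memory, Th17 and regulatory T cells and in activation surface genes, and below them in naive and homing genes. CCR6, a receptor of Th17 cells, stood at 54.4 against 1.43 CPM (5.22 ± 0.77), DUSP4, a phosphatase of MAP kinases, at 65.2 against 2.17 (4.91 ± 0.60), PRDM1, a factor of effector differentiation, at 193 against 15.3 (3.66 ± 0.52) and FAS at 67.7 against 9.81 (2.78 ± 0.31). Of 38 genes known to be higher in memory cells 26 were higher (32 adjusted over the list alone; adjusted p = 3.95e-34, and adjusted p = 0.0241 with an estimated correlation). Of 16 Th17 genes 9 were higher (adjusted p = 9.78e-07, and adjusted p = 0.101 with an estimated correlation; the same count over the list alone), with a list median of 3.44, or 2.54 with absent genes at their bound, and of 17 regulatory T cell genes 4 (9 adjusted over the list alone; adjusted p = 2.07e-06, and adjusted p = 0.0244 with an estimated correlation). Of 24 activation surface genes 10 were higher (13 adjusted over the list alone; adjusted p = 1.59e-08, and adjusted p = 0.0744 with an estimated correlation), TNFRSF4 by 3.29 ± 0.57 and IL2RA by 2.23 ± 0.41. CCR4 (3.58 ± 0.59), TNFRSF1B (2.22 ± 0.27), FOSL2 (2.82 ± 0.50) and the mitotic gene NUSAP1 (2.92 ± 0.45) were also higher. Of 26 naive and homing genes 14 were lower (19 adjusted over the list alone; adjusted p = 9.9e-15, and adjusted p = 0.044 with an estimated correlation); LRRN3 was lower by −3.28 ± 0.50, ADD2 by −4.80 ± 0.86 and CCR7 by −1.45 ± 0.37 (adjusted p = 0.0118). Ribosomal protein genes were lower in 10 of 53 (31 adjusted over the list alone; adjusted p = 5.07e-14, and adjusted p = 0.512 with an estimated correlation). Monocyte genes were higher in 12 of 22 (21 adjusted over the list alone; adjusted p = 5.37e-10, and adjusted p = 0.383 with an estimated correlation), and LTF, lactoferrin of neutrophil granules, was at least 907-fold higher, with no read in naive libraries. In all 1042 genes were higher and 443 lower, 70.2% higher (80.6% with scaling by library size alone). With the monocyte covariate 715 genes passed, 491 of them shared. Of 21 lists that passed at rest 12 kept the call with the covariate, among them the 6 described here other than the monocyte list. Without replicates 1, 2 and 4 the count of 1485 became 401, 899 and 851, and without naive day 0 replicates 1, 3 and 4 it became 869, 904 and 957. CCR7 did not pass with the covariate, without replicate 1 or 4, or without memory day 0 replicate 1.

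At day 1 the memory program stayed above that of naive cells and cytokines differed. MAF, a factor of IL-10 and IL-21 expression, stood at 818 against 34.4 CPM (4.57 ± 0.82), CXCR4, a homing receptor, at 210 against 16.7 (3.65 ± 0.44), CCR6 at 51.5 against 1.84 (4.81 ± 0.74) and PRDM1 at 169 against 13.7 (3.63 ± 0.52). Of 38 memory genes 28 were higher (34 adjusted over the list alone; adjusted p = 3.35e-31, and adjusted p = 0.0244 with an estimated correlation), FAS by 1.77 ± 0.30. Of 16 Th17 genes 11 were higher (15 adjusted over the list alone; adjusted p = 2.18e-10, and adjusted p = 0.0454 with an estimated correlation). Of 39 cytokine genes 16 were higher (18 adjusted over the list alone; adjusted p = 2.02e-08, and adjusted p = 0.232 with an estimated correlation), IL17A at 136 against 4.65 CPM (4.88 ± 1.14, adjusted p = 0.00758) and IL10 at 235 against 12.6 (4.22 ± 0.99, adjusted p = 0.00753), while IL2 stood at 65.6 against 81.7 (−0.32 ± 0.85, adjusted p = 0.861, lower in 3 of 4 donors). Naive day 1 replicate 2 held most of the naive reads of IL17A and IL10, at 15.4 and 41.6 CPM against 1.49 and 5.65 in the nearest library. Without it IL17A was higher by 6.98, IL10 by 6.29, MAF by 6.16 and CXCR4 by 4.73. The costimulatory receptor CD28 (2.22 ± 0.38), the adaptor SH2D1A (2.96 ± 0.33) and RASGRP1, which couples the receptor to RAS (1.79 ± 0.28), were higher, and CD27 (−1.97 ± 0.35), IL21R (−1.53 ± 0.24) and MYC (−1.44 ± 0.35) lower. KLF2 stood at 9.70 against 0.579 CPM (4.01 ± 0.87), and CTLA4 was higher by 2.12 ± 0.47 (3 of 4 donors). Replication histone genes were higher in 7 of 22 (11 adjusted over the list alone; adjusted p = 5.46e-07, and adjusted p = 0.429 with an estimated correlation), HIST1H1B by 1.87 ± 0.41. Ribosome assembly genes were lower in 4 of 34 (13 adjusted over the list alone; adjusted p = 9.62e-11, and adjusted p = 0.416 with an estimated correlation). Monocyte genes were higher in 15 of 22 (22 adjusted over the list alone; adjusted p = 4.57e-09, and adjusted p = 0.428 with an estimated correlation), with 3877 CPM of them in memory day 1 replicate 4. In all 988 genes were higher and 325 lower, 75.2% higher (86.0% with scaling by library size alone and 52.2% with limma-voom). The count of 1313 became 248 with the monocyte covariate and 525, 751 and 246 without replicates 1, 2 and 4. It became 570, 597 and 578 without naive day 1 replicates 1, 3 and 4, and 821 and 510 without memory day 1 replicates 2 and 4. Calls were lost for IL17A and IL10 in a fit of only these 8 libraries and without replicate 1, 3 or 4. CTLA4 was lost without replicate 1, MYC with the covariate, in the fit of 8 libraries and without replicate 2 or 4, and KLF2 with limma-voom, the covariate, and without replicate 4 or memory day 1 replicate 4.

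At day 5 memory cells stood above naive cells in memory, Th17 and cytokine genes. IL17A stood at 39.1 against 0.327 CPM (6.66 ± 1.35, adjusted p = 0.0106), MAF at 275 against 20.1 (3.77 ± 0.79, adjusted p = 0.0145), the calcium sensor NCALD at 31.9 against 1.99 (3.95 ± 0.57, adjusted p = 0.00101), PTPN13 at 22.4 against 0.471 (5.39 ± 1.11, adjusted p = 0.013) and CXCR6 at 47.2 against 1.95 (4.63 ± 1.00, adjusted p = 0.0153). NR4A2, an early response receptor of the nuclear receptor family (−2.67 ± 0.49), PGM2L1 (−2.88 ± 0.48) and the protease inhibitor SERPINE2 (−2.22 ± 0.45) were lower. Of 38 memory genes 6 were higher (21 adjusted over the list alone; adjusted p = 1.46e-16, and adjusted p = 0.0986 with an estimated correlation). Th17 genes were higher in 5 of 16 (11 adjusted over the list alone; adjusted p = 4.47e-10, and adjusted p = 0.0536 with an estimated correlation). Of 39 cytokine genes 4 were higher (18 adjusted over the list alone; adjusted p = 1.26e-07, and adjusted p = 0.281 with an estimated correlation). PTPN13 was higher by 9.12 and IL17A by 8.27 without naive day 5 replicate 3, and PGM2L1 was lower by −1.80 without naive day 5 replicate 4. In all 153 genes were higher and 76 lower, 66.8% higher (79.1% with scaling by library size alone). With the monocyte covariate 202 genes passed, against 248 at day 1, and with the donor block added 220 against 207. Chance cannot be excluded, as 5 of 35 splits of the 8 libraries called as many, the real one included. The 7 other splits that part all 4 donor pairs called at most 46, and the highest, 501, parts 2 pairs. In a fit of only these 8 libraries edgeR called 0 genes, none of the named ones, with 1069 at an unadjusted p under 0.05, while DESeq2 and limma-voom over all libraries called 472 and 218. The count of 229 became 6, 1, 398 and 7 without replicates 1 to 4. It became 92 and 409 without naive day 5 replicates 1 and 3, and 122, 99, 398 and 78 without memory day 5 replicates 1 to 4. NCALD was lost without replicate 2 and the other named genes without replicate 1, 2 or 4, IL17A and CXCR6 also with limma-voom, MAF and CXCR6 also without naive day 5 replicate 1, and CXCR6 also without memory day 5 replicate 1.

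At day 14 memory cells stood below naive cells in lymph node homing, histone and mitotic genes. CCR7 stood at 134 against 661 CPM (−2.30 ± 0.38, adjusted p = 0.00239), ACTN1, an actin cross-linker, at 7.67 against 74.1 (−3.28 ± 0.41), LRRN3 at 50.3 against 295 (−2.56 ± 0.48) and TCEA3 at 0.960 against 15.2 (−4.01 ± 0.58). Of 26 naive and homing genes 10 were lower (19 adjusted over the list alone; adjusted p = 4.46e-35, and adjusted p = 0.000746 with an estimated correlation). Of 22 replication histone genes 19 were lower (22 adjusted over the list alone; adjusted p = 1.24e-51, and adjusted p = 0.0155 with an estimated correlation), HIST1H1B at 409 against 2350 CPM (−2.52 ± 0.41). Of 34 G2 and M phase genes 10 were lower (30 adjusted over the list alone; adjusted p = 1.56e-42, and adjusted p = 0.0536 with an estimated correlation), CENPF by −2.26 ± 0.43 and TOP2A by −2.18 ± 0.43, and CDKN2C was lower by −2.41 ± 0.40. Without memory day 14 replicate 3, 31 of the 34 G2 and M phase genes were lower, adjusted over all genes. MKI67 stood at 76.8 against 334 CPM (−2.12 ± 0.58, adjusted p = 0.0684, and −1.99 with adjusted p = 0.0203 with the donor as a block). It also passed with DESeq2 and without replicate 4, naive day 14 replicate 4 or memory day 14 replicate 3. CCR6 was higher (3.73 ± 0.71), and 1 of 16 Th17 genes was higher (5 adjusted over the list alone; adjusted p = 5.32e-08, and adjusted p = 0.069 with an estimated correlation). B cell genes were higher in 4 of 14 (11 adjusted over the list alone; adjusted p = 2.16e-12, and adjusted p = 0.0744 with an estimated correlation), CD79A by 3.16 ± 0.67 in 3 of 4 donors. In all 56 genes were higher and 126 lower, 30.8% higher (41.6% with scaling by library size alone and 41.5% with DESeq2). Chance cannot be excluded, as 2 of 35 splits of the 8 libraries called as many, the real one included. The 7 other splits that part all 4 donor pairs called at most 15, and the highest, 673, parts 2 pairs. In a fit of only these 8 libraries edgeR called 0 genes, none of the named ones, with 1304 at an unadjusted p under 0.05, while DESeq2 and limma-voom over all libraries called 366 and 174. The count of 182 became 35, 2 and 317 without replicates 1, 2 and 3. It became 83, 78, 81 and 324 without naive day 14 replicates 1 to 4, and 78, 430 and 76 without memory day 14 replicates 2, 3 and 4. TCEA3 and LRRN3 were lost without replicate 2, and CENPF, HIST1H1B, CDKN2C, CCR6, TOP2A and CD79A without replicate 1 or 2. CD79A was also lost without replicate 4, TOP2A and CD79A without naive day 14 replicate 1 or memory day 14 replicate 4, CD79A without naive day 14 replicate 2, and CCR6 and CD79A without memory day 14 replicate 2.

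The response to activation differed between memory and naive cells in 150 genes at day 1, 68 more positive and 82 more negative in memory cells. DUSP4 was at 2.17 CPM at rest and 1161 at day 1 in naive cells, and at 65.2 and 779 in memory cells (difference −5.49 ± 0.76, adjusted p = 0.000296). PAQR4 went from 0.429 to 27.6 CPM in naive and from 7.26 to 25.9 in memory cells (−4.19 ± 0.55), and NR4A2 from 109 to 60.9 and from 244 to 9.30 (−3.87 ± 0.68). CXCR4 went from 687 to 16.7 CPM in naive and from 568 to 210 in memory cells (3.93 ± 0.58, or 5.00 without naive day 1 replicate 2), FBXO32, a subunit of a ubiquitin ligase, from 73.4 to 0.924 and from 49.1 to 8.87 (3.84 ± 0.51), and SH2D1A from 31.8 to 2.92 and from 28.7 to 22.9 (3.11 ± 0.44). IL6ST, the shared receptor chain of the IL-6 family (2.03 ± 0.35), the chromatin organiser SATB1 (2.44 ± 0.46) and RASGRP1 (2.08 ± 0.39, adjusted p = 0.00541) differed in the same direction. Of 34 G2 and M phase genes 5 were more negative in memory cells (16 adjusted over the list alone; adjusted p = 7.02e-13, and adjusted p = 0.383 with an estimated correlation). Early response factors were more negative in 2 of 29 (10 adjusted over the list alone; adjusted p = 4.07e-08, and adjusted p = 0.227 with an estimated correlation). Of 23 quiescence genes 3 were more positive (7 adjusted over the list alone; adjusted p = 6e-07, and adjusted p = 0.279 with an estimated correlation). With the donor as a block the count was 241. The splits (3 of 50 called as many, the real one included) cannot decide on chance. Without replicates 1 to 4 it was 37, 31, 90 and 37, without naive day 1 replicate 3 it was 97 and without memory day 1 replicate 2 it was 92. IL6ST was lost without replicate 4, SATB1 and RASGRP1 without replicate 1 and NR4A2 without replicate 2. It was 282 with the monocyte covariate, 237 in a fit of these 16 libraries alone, 411 with DESeq2 and 95 with limma-voom.

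At day 5 the responses differed in 158 genes, 39 more positive and 119 more negative in memory cells. DUSP4 went from 2.17 to 488 CPM in naive and from 65.2 to 365 in memory cells (−5.33 ± 0.76), NR4A2 from 109 to 158 and from 244 to 24.8 (−3.84 ± 0.67), TNFRSF1B, a receptor of TNF, from 33.6 to 260 and from 156 to 252 (−2.26 ± 0.36) and FAS from 9.81 to 57.3 and from 67.7 to 97.5 (−2.01 ± 0.41, adjusted p = 0.0116). FBXO32 went from 73.4 to 27.3 CPM in naive and from 49.1 to 154 in memory cells (3.08 ± 0.48). Of 38 memory genes 4 were more negative (13 adjusted over the list alone; adjusted p = 8.26e-10, and adjusted p = 0.232 with an estimated correlation). The resting libraries, uneven in monocyte genes, enter this difference. At rest the list median of memory against naive cells went from 2.53 to 1.4 with the monocyte covariate. Early response factors were more negative in 3 of 29 (13 adjusted over the list alone; adjusted p = 4.47e-10, and adjusted p = 0.138 with an estimated correlation). Activation surface genes were more negative in 3 of 24 (8 adjusted over the list alone; adjusted p = 5.32e-07, and adjusted p = 0.101 with an estimated correlation). All 4 groups are in batch 1. The splits (3 of 50 called as many, the real one included) cannot decide on chance. Without replicates 1, 2 and 4 the count became 3, 34 and 31, without naive day 0 replicates 1 and 2 it became 90 and 248, and without naive day 5 replicate 3 it became 242. FBXO32, TNFRSF1B, NR4A2 and FAS were lost without replicate 1, NR4A2 also without replicate 2 and FAS without replicate 4. It was 46 in a fit of these 16 libraries alone, where FAS was lost, 511 with DESeq2 and 92 with limma-voom.

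At day 14 the responses differed in 262 genes, 41 more positive and 221 more negative in memory cells. MKI67 went from 4.92 to 334 CPM in naive and from 36.1 to 76.8 in memory cells (−4.96 ± 0.85, adjusted p = 0.00191), TOP2A from 2.40 to 229 and from 11.5 to 50.4 (−4.43 ± 0.65), NUSAP1 from 2.05 to 107 and from 15.8 to 34.2 (−4.57 ± 0.60) and HIST1H1B from 1.03 to 2350 and from 2.76 to 409 (−3.92 ± 0.66). Of 34 G2 and M phase genes 24 were more negative in memory cells (29 adjusted over the list alone; adjusted p = 1.89e-47, and adjusted p = 0.0535 with an estimated correlation). Replication histone genes were more negative in 13 of 22 (16 adjusted over the list alone; adjusted p = 4.63e-26, and adjusted p = 0.0536 with an estimated correlation). CDKN2C (−3.52 ± 0.58), PAQR4 (−4.75 ± 0.56), DUSP4 (−4.88 ± 0.76), IL2RA (−3.01 ± 0.56), FAS (−2.22 ± 0.42) and IER2, an immediate early gene (−2.54 ± 0.43), also differed. Of 38 memory genes 13 were more negative (22 adjusted over the list alone; adjusted p = 1.55e-20, and adjusted p = 0.0536 with an estimated correlation). The resting libraries enter here too, as for DUSP4, IL2RA and FAS, higher in resting memory cells by 4.91, 2.23 and 2.78. Regulatory T cell genes were more negative in 2 of 17 (7 adjusted over the list alone; adjusted p = 5.61e-06, and adjusted p = 0.0254 with an estimated correlation). Without replicates 1, 2 and 4 the count became 18, 48 and 123, without naive day 0 replicates 1 and 3 it became 126 and 122, without naive day 14 replicates 1 and 3 it became 97 and 170, and without memory day 14 replicates 1 to 4 it became 172, 145, 427 and 103. MKI67, IER2, IL2RA, CDKN2C and FAS were lost without replicate 1, IL2RA and CDKN2C without replicate 2 and FAS without replicate 4. It was 521 with DESeq2, 168 with scaling by library size alone and 83 with limma-voom, where DUSP4 and HIST1H1B were lost.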

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

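The tests of the 3 patterns here were chosen after the results were seen.

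Small RNA genes were high and ribosomal protein genes low at days 1 and 14, and 3 explanations were weighed. The lowest small RNA share of batch 2 was 9.89 times the highest of batch 1, which fits a library batch. Dilution of ribosomal protein genes by small RNA was excluded: with small RNA genes left out of the totals, the lowest ribosomal protein share of batch 1 was still 1.37 times the highest of batch 2. For the small RNA genes the larger ratio of the day 5 to the day 14 change was −0.00945. Day 14 lies in batch 2, with far larger shares, so this ratio cannot decide. Within batch 1, from day 0 to day 5, their share went from 0.304% to 0.199% in naive and from 0.254% to 0.143% in memory cells. This lack of a rise argues against activation at any day for these genes. For ribosomal protein genes it stays open, as the share went from 36.2% to 27.8% in naive and from 27.5% to 23.7% in memory cells at day 5, 0.35 and 0.235 of the day 14 fall, and a response at days 1 and 14 alone cannot be told from the batch.

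Monocyte and granulocyte genes were high in resting memory libraries. All 22 of 22 monocyte genes were highest in the library with the largest sum of the others, which fits other blood cells in the isolated fraction. Whether they were the whole source of the memory list stays open, as the covariate holds monocyte genes only. NK cell genes summed to 785 ± 572 CPM (SD, n = 4) in resting memory and 122 ± 111 in resting naive cells. With the covariate the median log2 fold change of the 38 memory list genes went from 2.53 (SD 1.21) to 1.4 (SD 1.21), and the list still passed (adjusted p = 1.58e-17). As the source of most of it other blood cells stay open too, since 13 of 26 members past the threshold stayed past it.

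Genes of high GC content were up and those of low GC content down at days 1 and 14. The smallest difference across batches was 7.64 times the largest within a batch (1.68 against 0.22), which fits a library batch. Activation at any day was excluded: the larger day 5 difference was 0.0893 of the smaller day 14 difference. A response at days 1 and 14 alone cannot be told from the batch.

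In 303 tests of groups of 4 libraries, genes only with a group mean of at least 1 CPM, 44 had a library far from the others by Dixon's test, where chance gives about 1 in 20, or 15.2. Values are in CPM unless a percent is given, with the nearest other library in brackets. In resting naive cells these were, in replicate 2, plasma cell genes 446 (18.0), monocyte genes 2384 (376), BCL6 27.3 (14.2) and MYC 267 (173), and in replicate 4 GZMA 82.4 (20.5) and KLF2 1016 (650). Naive day 1 replicate 2 had monocyte genes 150 (27.8), dendritic cell genes 146 (34.9), CD8 cell genes 24.4 (5.6), GZMA 6.01 (1.3), IL10 41.6 (5.65), IL17A 15.4 (1.49) and IL4 3.23 (0.514), and replicate 3 had IL21 12.6 (3.23). Naive day 5 replicate 4 had IL2 33.2 (4.17), IL21 15.7 (0.696) and PDCD1 107 (35.7). Naive day 14 replicate 4 had plasma cell genes 70.3 (7.38), NK cell genes 593 (163), CD8 cell genes 47.6 (12) and platelet and red cell genes 67.2 (4.95). The same group had CD40LG 41.6 (26.6) in replicate 3 and IL7R 128 (259) in replicate 2. Resting memory replicate 1 had monocyte genes 31140 (7616), replicate 2 had IL10 5.30 (1.33), IL17A 4.92 (0.540) and IL22 16.3 (0.111), and replicate 4 had GZMA 270 (78.7), GZMB 25.1 (14.0) and TBX21 39.2 (13.0). Memory day 1 replicate 4 had small RNA genes 11.9% (5.6%), monocyte genes 3877 (486), NK cell genes 1158 (220), IL13 16.1 (72.2) and KLF2 30.6 (3.86). Replicate 2 had ribosomal protein genes 7.66% (9.66%) and replicate 1 had IL22 28.8 (5.22). Memory day 5 replicate 1 had small RNA genes 0.188% (0.132%), replication histone genes 0.107% (0.0697%) and LAG3 736 (1303), replicate 4 had IFNG 418 (85.9) and replicate 3 had S1PR1 51.2 (137). Memory day 14 replicate 4 had CD8 cell genes 314 (28.4) and replicate 3 had KLF2 48.2 (183).

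A test of the difference between the responses of memory and naive cells was passed by 150, 158 and 262 genes at days 1, 5 and 14. At day 1 the differences in log2 fold change were DUSP4 −5.49, PAQR4 −4.19, NR4A2 −3.87, CXCR4 3.93, FBXO32 3.84, SH2D1A 3.11, SATB1 2.44, RASGRP1 2.08 and IL6ST 2.03. At day 5 they were DUSP4 −5.33, NR4A2 −3.84, TNFRSF1B −2.26, FAS −2.01 and FBXO32 3.08. At day 14 they were MKI67 −4.96, DUSP4 −4.88, PAQR4 −4.75, NUSAP1 −4.57, TOP2A −4.43, HIST1H1B −3.92, CDKN2C −3.52, IL2RA −3.01, IER2 −2.54 and FAS −2.22.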

How the results depend on the processing

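The alternatives were followed for 140 genes of the text, in 273 pairs of a gene and a comparison. Of these pairs 267 were called, 228 of them in every alternative fit that gave an adjusted p, at most 26 for 2 groups and 34 for a difference of responses. The other 39 lost the call somewhere. Genes whose calls held were preferred for naming, so these counts do not speak for all genes. With 1 library left out, 75 of the 273 fold changes moved by over 1.5-fold and 36 of them by over 2-fold; the latter stand in the text or lost the call there. None of the 267 called pairs reversed, and MKI67 gained a call in 2 comparisons. The monocyte covariate, GC removal and block combinations were chosen after the results were seen.

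For the difference in the day 14 response, 262 genes became 168 with library size only, 521 with DESeq2, 83 with limma-voom, and 18 to 427 with libraries left out. For that at day 5, 158 became 511 with DESeq2, 92 with limma-voom, 46 with only the libraries compared and 3 to 248 with libraries left out. With the replicate block it became 73 with only those libraries, 104 with the covariate and 242 with the GC trend removed. For that at day 1, 150 became 411 with DESeq2, 95 with limma-voom, 237 with only the libraries compared, 282 with the covariate and 31 to 169 with libraries left out. With the replicate block it became 241, and 354, 341 and 226 with only those libraries, the covariate and the GC trend removed.

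For memory against naive at day 5, 229 became 472 with DESeq2, 0 with only the libraries compared by edgeR (1069 at unadjusted p under 0.05; limma-voom over all libraries 218), 14 with the replicate block added, and 1 to 409 with libraries left out. At day 14, 182 became 366 with DESeq2, 0 with only the libraries compared (1304 unadjusted; limma-voom 174), 0 with the replicate block added (1391 unadjusted), and 2 to 430 with libraries left out. At day 0, 1485 became 715 with the covariate, 292 with the replicate block added, and 401 to 1476 with libraries left out. At day 1, 1313 became 248 with the covariate, 207 with the replicate block added, and 246 to 1619 with libraries left out.

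Memory day 5 against day 0 went from 6946 to 3750 with the covariate and 2942 with the replicate block added, and memory day 14 from 8510 to 5363 and 4122. Memory day 14 against day 1 ran from 2006 to 5532, against 4660. Of 255 list calls, 9 passed with an estimated correlation. The replicate block alone changed the calls of MKI67 at day 14 in memory cells and against naive cells. It also changed that of the memory day 5 list of lysine 4 enzymes, and no other call of a named gene. Calls of the other lists printed here held, apart from the S phase list of memory day 14 against day 1, which was not followed. For each moved result the cause was not tested; fits of fewer libraries also have fewer degrees of freedom.

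With library size only, the median log2 fold change of all genes went from 0.03 to 0.42 and from 0.00 to 0.34 in naive cells at days 1 and 14, and from 0.04 to 0.38 and 0.02 to 0.40 in memory cells. Alternatives for files without counts (pseudocounts and filters on RPKM) and for symbols with several features were not run, since neither case arose.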

Other observations

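Genes of chromatin enzymes moved within batch 1 at day 5. EZH2, which methylates histone H3 at lysine 27, stood at 151 against 13.8 CPM in naive cells (3.46 ± 0.36) and 133 against 25.6 in memory cells (2.37 ± 0.35), and its partner EED was higher by 2.81 ± 0.36 and 3.23 ± 0.37. SETD1B, a methyltransferase of lysine 4, was lower by −3.18 ± 0.26 and −2.17 ± 0.25, and MLL3 by −1.57 ± 0.19 and −1.29 ± 0.19. In naive cells the methylcytosine oxidase TET1 (−2.47 ± 0.41) and the methyltransferase ASH1L (−1.57 ± 0.20) were lower. Of 21 genes of lysine 4 enzymes 6 were higher and 10 lower in naive cells (camera adjusted p = 0.0951) and 2 and 8 in memory cells (0.0505, and 0.0491 with the replicate block). Of 18 genes of repressive enzymes 5 were higher and 7 lower in both cell types (0.999 and 0.619; 6 and 7 in memory cells adjusted over the list alone). The memory list of lysine 4 enzymes also passed with the covariate (0.0328), with the GC trend removed (0.0435) and without replicate 2 (0.049). Genes of the response to low oxygen rose in naive cells, VEGFA 48.5-fold (adjusted p = 7.26e-06), ADM by 7.06 ± 1.54 and ANGPTL4, which acts on lipid uptake, by 8.21 ± 1.45. ANGPTL4 rose by 9.03 ± 1.46 in memory cells. In naive cells ANGPTL4 rose by 10.19 and VEGFA by 6.96 log2 units without day 0 replicate 2, and ADM by 8.93 without day 0 replicate 1. In memory cells ANGPTL4 rose by 11.05 without day 0 replicate 4. Of 17 such genes 11 rose and 1 fell in naive cells (12 and 1 adjusted over the list alone; adjusted p = 0.0406, and adjusted p = 0.654 with an estimated correlation). This list did not pass with the covariate (0.0546) or without replicate 3 (0.0688) or 4 (0.0773). In memory cells 9 rose and 2 fell (0.0954, and 0.00759 without replicate 1).

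Chaperone genes fell from day 1 to day 14. HSPD1, the mitochondrial chaperonin, fell from 1190 to 127 CPM in naive cells (−3.24 ± 0.45), HSP90AA1 by −2.26 ± 0.34 in naive and −1.50 ± 0.33 in memory cells, and HSPE1 by −2.04 ± 0.43 in memory cells. Of 13 such genes 7 fell in naive cells (adjusted p = 0.00921, and adjusted p = 0.509 with an estimated correlation). In memory cells 7 fell (8 adjusted over the list alone; adjusted p = 0.00159, and adjusted p = 0.383 with an estimated correlation). Genes of antigen receptor signalling rose: CD28 by 2.02 ± 0.37 and the kinase PRKCQ by 1.81 ± 0.24 in naive cells, and the phospholipase PLCG1 by 1.27 ± 0.21 in memory cells. In naive cells 14 of 26 rose and 3 fell (15 and 3 adjusted over the list alone; adjusted p = 0.000889, and adjusted p = 0.444 with an estimated correlation). In memory cells 10 rose and 2 fell (adjusted p = 0.0426, and adjusted p = 0.677 with an estimated correlation). The memory list did not pass with the covariate (0.109), without replicate 1, 2 or 4 (0.168, 0.0791 and 0.192) or without memory day 1 replicate 4 (0.131).

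The split tests below were chosen before the results were seen. The libraries of each comparison were regrouped in every other way into groups of the same size, or in 50 splits, drawn at random but for the real one, for the 3 differences of response. Only 1 of 35 splits, the real one, called as many genes (share 0.0286) in the 8 comparisons over time and in memory against naive cells at days 0 and 1. The highest other split called 3, 793 and 86 genes for naive days 1, 5 and 14, 3539, 757 and 1215 for memory cells, 18 and 4517 for day 14 against day 1, and 232 and 373 for memory against naive. Among the splits that part as many donor pairs as the real one, the highest were 0, 235 and 47; 2308, 466 and 1215; 0 and 273; and 1 and 0. At days 5 and 14 of memory against naive, 5 and 2 splits of 35 called as many (highest 501 and 673, both parting 2 donor pairs, or 46 and 15 among the 7 others parting all 4), so chance cannot be excluded. Splits that part all 4 pairs are too few for a share under 0.05. For the differences of response, 3, 3 and 1 of 50 splits called as many, with highest others of 2925, 369 and 180 (2925, 349 and 0 among those parting as many pairs). Chance cannot be excluded at days 1 and 5, and splits that call more genes than the real one point to structure among the samples.

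Donors left a mark on the counts. Deviations from the group means correlated at 0.127 on average for 112 pairs of libraries of the same donor and at −0.042 for pairs of other donors in other groups.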
